A study of Homo sapiens with 8 samples.

How the data were processed

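RNA was measured in 8 libraries from 2 established human ovarian cancer lines, SKOV3 and A2780. Each line was transfected with a negative control siRNA or with an siRNA against Bcl2l10 for 48 hours, with 2 libraries per group. Groups and replicate numbers were taken from the sample titles, and the knockdown columns, which carry the gene's other name Diva, were matched to those titles. Per the labels' protocols, total RNA was isolated with Trizol and libraries were made with a stranded SMARTer kit. The labels do not say whether libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

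The authors deposited one table per line. Per the file headers, each table holds log2 FPKM values (fragments scaled by transcript length and by library size) for each library. The values themselves show that the deposited log2 values are log2(FPKM + 1): after removal of an offset of 1, 100% of values above 0.01 had at most 6 significant digits (tolerance 1e-09, relative above an FPKM of 1). The tables also hold the authors' group means, log2 fold changes and p-values, and their own test is not given in the sources used here. Besides the group fold change, the headers list a log2 fold change for each pair of libraries of equal number. Per the submitters' processing notes, the build was hg19 and the tools were FastQC, TopHat, bedtools, Cufflinks and edgeR, with no version or role. Each table has 26254 genes, of which 2286 are small RNAs, and 95 rows list several gene IDs. In all, 8906 rows share their listed region with another row, so overlapping genes are uncertain. How the authors used strand is not given in the sources used here. No column of per-sample values was left unmapped.

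FPKM values are not counts, and no count test was run. Absolute depth is unknown, but low values keep the relative depth of libraries within a table, since a gene's lowest values are multiples of 1 fragment. Among 1020 to 1342 low genes (FPKM up to 0.1) per pair of libraries, 75.6 to 79.3% of ratios lay within 0.05 (log2) of a small whole-number ratio at the best depth, against 26.9 to 28.3% by chance. Relative to the first control library, depth in SKOV3 was 1.09 in the second control library and 0.748 and 0.712 in the knockdown libraries. In A2780 it was 1.12 in the second control library and 1.46 and 1.44 in the knockdown libraries. Shallower libraries give larger counting error at low FPKM. Small RNAs, whose FPKM is unreliable because of their length, took 34.9 to 52.8% of the summed FPKM. They were counted in the tests and are not named.

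The main test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(FPKM + 1) within each line, over genes with an FPKM of at least 1 in at least 2 of the 4 libraries. Fold changes are on this log2(FPKM + 1) scale, which understates the change of low genes. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Each line's fit had 2 residual degrees of freedom, to which limma adds information from all genes. An exact permutation test of 2 against 2 libraries cannot give a two-sided p below 0.333. The difference of the siRNA effect between the lines was tested in one fit of the 4 group means over all 8 libraries (4 residual degrees of freedom), as the A2780 effect minus the SKOV3 effect. The tables were normalized separately, so levels were not tested between lines. Overlap of calls was set against n1 × n2 / N and tested with Fisher's exact test; the lines share no control library.

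The 25 gene lists and the choice of tests were fixed before the data were examined. Lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry. With an estimated correlation, camera uses only the fit's residual degrees of freedom (2 per line, 4 for the difference), so few lists can pass. For NF-kB genes in SKOV3 that correlation was −0.059, below the preset, yet the unadjusted camera p went from 4.9e-06 to 0.040. A call lost with it therefore does not by itself show that correlated genes made the call. For the other lists called, the estimate lay above the preset. It was 0.027 (ATF4) to 0.55 (glycolysis) in SKOV3, with 0.50 for hypoxia. In A2780 it was 0.025 for pentose phosphate and NRF2, 0.27 for cytosolic ribosomal proteins, 0.87 for G2/M and 0.94 for interferon. In those lists correlated genes may have made the call, and this cannot be told apart from the few degrees of freedom. The lists covered the TCA cycle, glycolysis, respiratory complex I, complexes III to V, mitochondrially encoded mRNAs, and glutamine and serine metabolism. Others were the ATF4 response, the ER unfolded protein response, the BCL2 family, p53 targets, G2/M, S phase and replication-dependent histones. Further lists held the type I interferon response, NF-kB, cholesterol, fatty acids, hypoxia, pentose phosphate and NRF2 targets, and autophagy. The rest were cytosolic and mitochondrial ribosomal proteins, and epithelial, mesenchymal, and leukocyte and endothelial markers. Named genes followed a fixed rule. It took BCL2L10, SDHD and IDH1, the 10 largest rises and 10 largest falls per line among called genes with no overlap between groups, and up to 4 members with the smallest p of each list described. Which lists to describe with members was decided after the list results were seen. Some genes that the rule takes are not reported here, and no others were put in their place. It also took the 5 largest differences between lines per direction and the 5 genes per direction with the largest smaller fold in both lines.

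The tests were checked on simulated data with known changes. In SKOV3 (12087 genes simulated), 3.03%, 58.2% and 89.6% of genes changed by 0.5, 1 and 2 on the log2 scale were recovered. In A2780 (11569 genes), the shares were 6.06%, 62.7% and 82.1%, and for the difference between the lines (10420 genes) 21.2%, 77.6% and 94.0%. False calls numbered 4 or 5 in each. The simulated noise was independent between genes, with no deviation shared within a library, so these shares and false calls hold for that setting only. The alternatives were pseudocounts of 0.1 and 0.5, no filter, a filter at FPKM 5, median-of-ratios scaling, quantile normalization, eBayes without trend and with robust weights, a replicate block, 1 fit over all 8 libraries, and each library left out. Summing the rows of a symbol changes nothing, since no symbol has several rows, and alternatives that need counts were not run.

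For the closing section, the longest annotated 3' UTR of each gene was taken from GENCODE v29 (GRCh38) by symbol. It was found for 90.8% of genes tested in SKOV3 and 91.0% in A2780. The log2 fold change, limited to 2 in size, was regressed on the presence of each of the 16384 words of 7 bases, with UTR length and GC content and their squares in the model, for words in at least 30 genes. The word search was first explored on genes of higher expression and then run on all tested genes with a 3' UTR. In a check on shuffled fold changes, a planted word ranked 1st in both lines. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used.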

Results

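The series profiled RNA in SKOV3 and A2780, cell lines derived from human ovarian cancers, 48 hours after transfection with an siRNA against Bcl2l10 or a control siRNA. BCL2L10, also called Diva, is a member of the BCL2 family of apoptosis regulators. The series title names SDHD and IDH1, both in the TCA cycle list tested here, as regulated by it. The comparisons ask which transcripts changed in each line and whether the lines responded alike. Each of the 4 groups held 2 libraries. Of 26254 genes, 16631 to 17762 had an FPKM above 0 per library and 11350 to 11986 an FPKM of at least 1. Within SKOV3 the knockdown libraries were shallower than the first control library (0.748 and 0.712 of its depth), and within A2780 they were deeper (1.46 and 1.44 times).

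The targeted gene could not be used to check the knockdown. BCL2L10 (hg19, chromosome 15, 52401465 to 52404972) was listed at an FPKM of 0 in 7 libraries and at 0.0456 in SKOV3 control library 1. With a trace value in a single control library and 0 elsewhere, no fold change was computed. In the authors' deposited table its log2 fold change was −0.03 in SKOV3 and 0 in A2780, each with a p of 1.

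SDHD, a membrane anchor subunit of succinate dehydrogenase, fell in both lines. In SKOV3 its FPKM was 35.4 ± 1.02 (SD, n = 2) in the controls and 4.50 ± 0.65 after the siRNA, a log2 fold change of −2.73 (SE 0.11, limma adjusted p = 0.00027). In A2780 it was 36.7 ± 5.09 and 9.47 ± 0.44, a log2 fold change of −1.84 (SE 0.12, adjusted p = 0.011). IDH1, the cytosolic NADP-dependent isocitrate dehydrogenase, fell from 72.7 ± 5.29 to 13.3 ± 0.92 in SKOV3 (log2 fold change −2.36, SE 0.10, adjusted p = 0.00027). In A2780 it fell from 46.6 ± 1.82 to 14.6 ± 2.31 (log2 fold change −1.62, SE 0.12, adjusted p = 0.011). SDHD lies on chromosome 11 (hg19, 111957547 to 111966525) and IDH1 on chromosome 2 (209100950 to 209119867). The authors' deposited table gives log2 fold changes of −2.73 and −1.85 for SDHD and −2.36 and −1.61 for IDH1 in SKOV3 and A2780, all with p = 5e-05. That is the lowest p the authors list in either line, held by 994 genes in SKOV3 and 426 in A2780. Without a filter on low values the adjusted p of both genes in A2780 was 0.0553 and missed the threshold; it lay between 0.000186 and 0.0442 under the other alternatives.

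**Figure D1:**
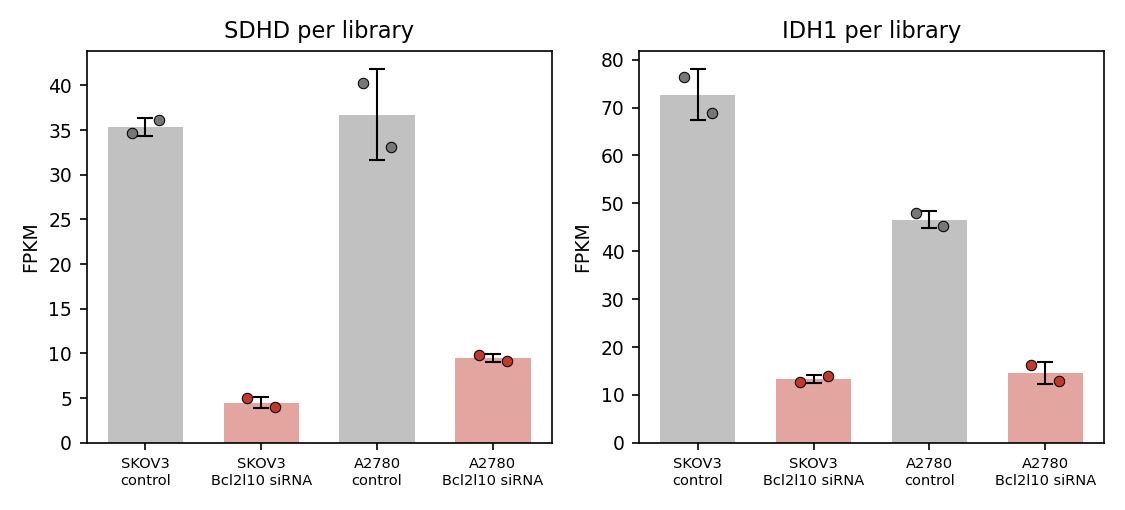
FPKM of SDHD and IDH1 in each library (points), with group means (bars) and SD (error bars, n = 2). Both genes were lower in every knockdown library than in any control library of the same line; levels of the 2 lines come from tables normalized separately.

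The TCA cycle list did not pass camera in either line, with SDHD and IDH1 or without them. In SKOV3, 3 of the 28 measured members of the TCA list rose and 5 fell, and the same numbers held when adjusted over the list alone. OGDH, a subunit of the 2-oxoglutarate dehydrogenase complex, changed by −1.23 (log2, SE 0.14, adjusted p = 0.0035). The list's median log2 fold change was 0.04, its mean −0.17, and camera gave an adjusted p of 0.85. Without SDHD and IDH1, 3 of 26 rose and 3 fell (median 0.07, camera adjusted p = 0.635, direction up). In A2780, 4 of 27 members rose and 3 fell (4 and 3 adjusted over the list alone; median 0.10, mean −0.02, camera adjusted p = 0.47, direction up), and without SDHD and IDH1 4 of 25 rose and 1 fell (median 0.11, camera adjusted p = 0.129, direction up). SDHB, the iron-sulfur subunit of succinate dehydrogenase, rose by 0.60 (SE 0.08, adjusted p = 0.019); its call was lost when either A2780 control library or knockdown library 2 was left out. The title's genes may have been chosen on these samples, so their place in the list is not independent evidence.

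In SKOV3, the siRNA changed 3016 of 12087 genes by limma (1402 higher, 1614 lower; 4840 at an unadjusted p under 0.05). CXCL8, which encodes the neutrophil chemokine interleukin-8, had the largest fall (FPKM 17.0 ± 2.13 to 1.46 ± 0.85, log2 fold change −2.91, SE 0.24, adjusted p = 0.0014). It was followed by SDHD, the adhesion adaptor gene FERMT2 (−2.73), the translation factor gene EIF4G2 (−2.72), SWAP70 (−2.64), ATP6V1D, a subunit of the vacuolar proton pump (−2.55), and GDF15, a stress-induced cytokine (−2.48). ENOPH1 (−2.40), IDH1 and C14orf142 (−2.29) completed the 10 largest falls, with SE from 0.08 to 0.24. The largest rise was in TPM4, an actin-binding tropomyosin (160 ± 15 to 919 ± 179 FPKM, log2 fold change 2.51, SE 0.15, adjusted p = 0.00068). DNAJC25-GNG10, a readthrough gene whose reads overlap its neighbours' and is uncertain, rose by 2.26. The glycoprotein gene CCDC80 (1.99), the glucosidase subunit gene GANAB (1.93), TNNT2 (1.87), the IGF-binding protein gene IGFBP3 (1.83), EMC6 (1.83), the keratin gene KRT17 (1.82), the collagen gene COL8A1 (1.79) and TRIB2 (1.76) also rose, with SE from 0.10 to 0.33. The groups did not overlap in 66.9% of tested genes, against 33.3% by chance. The count was 906 without control library 1, 1366 without control library 2, 1984 without knockdown library 2 and 1356 without a filter on low values. CCDC80 (adjusted p = 0.058) and COL8A1 (0.053) lost their calls without control library 1, and both, with KRT17, did so without a filter.

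Many genes of glycolysis and hypoxia rose in SKOV3 after the siRNA. Of 24 glycolysis genes, 14 rose and none fell (16 and 0 adjusted over the list alone; camera adjusted p = 5.3e-05, adjusted p = 0.55 with an estimated correlation). HK2, a hexokinase, rose from 5.35 to 15.1 FPKM (log2 fold change 1.33, SE 0.15), PFKL, the liver phosphofructokinase, by 1.22 (SE 0.15), GPI by 0.72 (SE 0.10) and PDK1, which inhibits pyruvate dehydrogenase, by 0.66 (SE 0.11). PDK1 was not called without control library 1 (adjusted p = 0.061) or control library 2 (0.052). Of 18 hypoxia targets, 12 rose and 3 fell (12 and 3 adjusted over the list alone; camera adjusted p = 0.010, adjusted p = 0.64 with an estimated correlation). ERO1A rose by 1.22, P4HA1 by 1.15 and ADM, which encodes the vasodilator adrenomedullin, by 0.92, whereas MXI1 changed by −2.18. Between the 2 SKOV3 knockdown libraries, library 2 exceeded library 1 by a list median of 0.27 for glycolysis and 0.25 for hypoxia; between the controls these gaps were −0.06 and −0.03.

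A number of genes of amino acid and oxidative stress responses fell in SKOV3. Of 26 ATF4 and integrated stress response genes, 13 fell and 3 rose (16 and 4 adjusted over the list alone; camera adjusted p = 0.00013, adjusted p = 0.53 with an estimated correlation). WARS, the tryptophanyl-tRNA synthetase, fell from 110 to 22.0 FPKM (log2 fold change −2.27, SE 0.09), NUPR1 changed by −1.88, ATF3 by −1.53 and DDIT3, which encodes CHOP, by −1.14. Of 19 genes of glutamine, serine and one-carbon metabolism, 8 fell and 1 rose, the same adjusted over the list alone (camera adjusted p = 0.039, adjusted p = 0.55 with an estimated correlation, and 0.060 without control library 1). PHGDH, the first enzyme of serine synthesis, changed by −2.18, PSAT1 by −1.13, MTHFD2 by −0.71 and GLUD1 by −0.68. Of 22 pentose phosphate and NRF2 target genes, 10 fell and none rose (14 and 1 adjusted over the list alone; camera adjusted p = 0.00042, adjusted p = 0.53 with an estimated correlation). They included OSGIN1 (−1.28), SRXN1 (−0.79) and the aldo-keto reductase genes AKR1C2 (−1.03) and AKR1C3 (−0.96), close paralogs whose reads may be shared. Of 25 autophagy and lysosome genes, 10 fell and 3 rose (11 and 3 adjusted over the list alone; camera adjusted p = 0.033, adjusted p = 0.55 with an estimated correlation, and 0.088 without knockdown library 1). SQSTM1, the autophagy receptor p62, fell from 388 to 125 FPKM (log2 fold change −1.63), LAMP2 changed by −0.87 and BECN1 by 0.61.

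Many inflammatory and interferon genes also fell in SKOV3. Of 13 measured NF-kB and cytokine genes, 7 fell and none rose (12 and 1 adjusted over the list alone; camera adjusted p = 5.3e-05, adjusted p = 0.53 with an estimated correlation). IL1A, which encodes interleukin-1 alpha, fell from 3.93 to 0.13 FPKM (log2 fold change −2.12), the NF-kB inhibitor gene TNFAIP3 changed by −1.62 and CXCL2 by −1.46. Of 24 type I interferon response genes, 14 fell and 1 rose (15 and 1 adjusted over the list alone; camera adjusted p = 5.3e-05, adjusted p = 0.53 with an estimated correlation). IFIT3 changed by −1.34, ISG15 by −1.24 and PARP9 by −0.75.

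Some cell cycle and cholesterol genes rose in SKOV3. Of 27 G2/M genes 12 rose and none fell (14 and 1 adjusted over the list alone; camera adjusted p = 0.0039, adjusted p = 0.53 with an estimated correlation), with CENPA at 0.49, KIF2C at 0.43, CCNB1 at 0.41 and TPX2 at 0.35. Of 29 S phase genes 8 rose and none fell (9 and 0 adjusted over the list alone; camera adjusted p = 0.0019, adjusted p = 0.53 with an estimated correlation). RRM2, a ribonucleotide reductase subunit, rose by 0.79, GINS2 by 0.65, TYMS by 0.51 and GINS1 by 0.35. Of these 8 named genes, RRM2 was called with each SKOV3 library left out; the other 7 were not called without control library 1, nor, TYMS aside, without control library 2. CCNB1, CENPA, TPX2 and GINS1 were not called without knockdown library 1, nor TPX2 and GINS1 without knockdown library 2. Of 24 cholesterol genes 6 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.020, adjusted p = 0.55 with an estimated correlation, and 0.10 without control library 2). FDPS, which encodes farnesyl diphosphate synthase, rose by 0.82, and IDI1 changed by −0.98. In the BCL2 family, 4 of 19 measured genes rose and 6 fell, the same adjusted over the list alone (camera adjusted p = 0.85). BNIP3L rose by 1.26, while the survival gene MCL1 changed by −1.10 and the pro-apoptotic genes BMF and HRK by −1.40 and −1.35.

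The other lists did not pass camera in SKOV3. Of 23 p53 targets 2 rose and 9 fell (adjusted p = 0.073), of 17 ER unfolded protein response genes none rose and 3 fell (0.073), and of 11 histone genes 1 rose (0.072). The p53 list passed without control library 1 (0.045) or knockdown library 1 (0.023), and so did histones (0.00015 and 0.025); with a replicate block they passed as well (0.025 and 0.018). Complex I (4 rose and 1 fell of 37, adjusted p = 0.23), complexes III to V (3 and 2 of 34, 0.33) and the mitochondrial ribosome (4 and 1 of 37, 0.31) did not pass. Neither did fatty acid genes (3 and 2 of 24, 0.85), cytosolic ribosomal proteins (0 and 2 of 51, 0.69), epithelial markers (4 and 1 of 13, 0.33) and mesenchymal genes (4 and 3 of 22, 0.87). For mesenchymal genes the median was 0.15, the mean −0.01 and camera's direction up, and for fatty acid genes −0.03, 0.01 and up. Knockdown library 2 exceeded library 1 by a list median of 0.45 for mesenchymal genes. Of 15 leukocyte and endothelial markers, 1 passed the filter in each line, and none of the 13 mitochondrially encoded mRNAs of the list is in the tables.

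In A2780, the siRNA changed 1581 of 11569 genes by limma (849 higher, 732 lower; 3924 at an unadjusted p under 0.05). IL32, which encodes a proinflammatory cytokine, had the largest fall (FPKM 15.8 ± 7.11 to 1.84 ± 0.75, log2 fold change −2.52, SE 0.34, adjusted p = 0.021). It was followed by the chloride channel gene CLIC4 (−2.19), LIN7C (−2.10), ELOVL4, a fatty acid elongase (−2.0), the acute phase gene SAA2 (−2.0), which has close paralogs, CD164 (−1.87), PRTG (−1.87), the apoptosis inhibitor gene BIRC3 (−1.85), SDHD and WRB (−1.76). Their SE ranged from 0.08 to 0.34. COL1A1, a chain of type I collagen, had the largest rise (4.04 ± 1.27 to 22.6 ± 11.4 FPKM, log2 fold change 2.16, SE 0.38, adjusted p = 0.031). The imprinted gene PHLDA2 (2.02), IER3 (1.85), TPM4 (1.85), the osteopontin gene SPP1 (1.75), TMEM158 (1.74), EGR3 (1.70), the spermine oxidase gene SMOX (1.66), ZNF267 (1.65) and the chemokine receptor gene CXCR4 (1.64) also rose, with SE from 0.10 to 0.25. The groups did not overlap in 62.9% of tested genes, against 33.3% by chance. The count fell to 161 without control library 1, 167 without control library 2, 625 without knockdown library 2 and 4 without a filter on low values, and was 2485 in 1 fit over all 8 libraries and 4667 with a replicate block. Without control library 1, COL1A1, IER3, SPP1, SMOX, TMEM158, SAA2 and PRTG lost their calls, and without control library 2, COL1A1, CXCR4 and TMEM158 did.

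Some interferon genes fell in A2780 too. Of 24 members 8 fell and none rose (9 and 0 adjusted over the list alone; camera adjusted p = 0.013, adjusted p = 0.93 with an estimated correlation). PARP9 fell from 31.5 to 15.2 FPKM (log2 fold change −1.02, SE 0.16), IRF9 changed by −0.93 and STAT2 by −0.66. Library 2 exceeded library 1 by a list median of 0.52 in the controls and 0.56 in the knockdown, about the size of the median change of −0.54. The list was not called without control library 2 (adjusted p = 0.17) or knockdown library 1 (0.13), and PARP9, IRF9 and STAT2 lost their calls without either control library, STAT2 also without knockdown library 1. Of 27 G2/M genes 2 fell and none rose (1 and 0 adjusted over the list alone; camera adjusted p = 0.013, adjusted p = 0.93 with an estimated correlation). NUSAP1 changed by −1.04 and TTK by −0.46, while KIF20A (−0.54) and TOP2A (−0.54) did not pass the test. Here library 2 was lower than library 1 by −0.25 in the controls and −0.26 in the knockdown. The list's adjusted p was 0.12 without control library 1 and 0.18 without knockdown library 2; NUSAP1 was not called without control library 1, nor TTK without any library but knockdown library 1. None of 29 S phase genes was called by limma, and camera gave an adjusted p of 0.14, but 0.0037 without control library 2 and 0.0049 without knockdown library 1 (gaps of −0.22 and −0.24). Of 51 cytosolic ribosomal protein genes none was called, with a median of −0.11 (camera adjusted p = 0.025, adjusted p = 0.93 with an estimated correlation). That call was lost without control library 2 (0.39) or knockdown library 1 (0.32).

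Some genes of redox metabolism rose in A2780, and the ATF4, hypoxia and glycolysis lists did not pass camera. Of 17 pentose phosphate and NRF2 target genes 5 rose and none fell, the same adjusted over the list alone (camera adjusted p = 0.048, adjusted p = 0.93 with an estimated correlation). The quinone reductase gene NQO1 rose by 0.50, SLC7A11, the cystine transporter gene, by 0.43, TKT by 0.43 and TXNRD1 by 0.39. The list's adjusted p was 0.065 without control library 1, 0.066 without knockdown library 2 and 0.053 with median-of-ratios scaling. SLC7A11, TKT and TXNRD1 were not called without any 1 of the 4 libraries, nor NQO1 without either control library or knockdown library 2. Of 26 ATF4 genes 6 rose and 1 fell (9 and 4 adjusted over the list alone; camera adjusted p = 0.26). TRIB3 rose from 7.02 to 16.9 FPKM (log2 fold change 1.16, SE 0.08), SLC7A5 by 0.53 and DDIT4 by 0.47, and CHAC1 changed by −0.75. SLC7A5 and DDIT4 were not called without any 1 of the 4 libraries, nor CHAC1 without either control library. In the hypoxia list 5 of 19 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.055), with BHLHE40 at 1.30, SLC2A3 at 1.00, ADM at 1.00 and MXI1 at −1.21. Of 24 glycolysis genes 4 rose and none fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.059), namely PFKL (0.82), SLC2A1 (0.69), PFKFB3 (0.58) and HK1 (0.48). Hypoxia and glycolysis passed camera without control library 1 (0.031 and 0.031) or knockdown library 2 (0.0071 and 0.040), and glycolysis with a replicate block (0.043). Without either control library, ADM, MXI1 and the 4 glycolysis genes lost their calls, PFKFB3 also without knockdown library 1 and HK1 without knockdown library 2.

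Among p53 targets in A2780, 7 of 23 fell and none rose, the same adjusted over the list alone (camera adjusted p = 0.050, which just missed the threshold). TP53INP1 changed by −1.74, SESN1 by −1.35, CCNG1 by −0.84 and the death receptor gene TNFRSF10B by −0.58; in this list library 2 exceeded library 1 by 0.24 in the controls and 0.23 in the knockdown. Of 20 mesenchymal and matrix genes 3 rose and none fell, the same adjusted over the list alone (camera adjusted p = 0.050, which just missed the threshold, and 0.0036 with a replicate block). COL6A3 rose by 0.88 and SNAI2 by 0.58, while ITGA5 at 0.65 was not called; library 2 exceeded library 1 by 0.34 in both groups. The p53 list passed without control library 1 (0.00097) or knockdown library 2 (0.00072), and the mesenchymal list without control library 2 (0.0026) or knockdown library 1 (0.00025). CCNG1 and COL6A3 were not called without control library 1, TNFRSF10B without either control library, and SNAI2 without either or knockdown library 2. In the BCL2 family 1 of 15 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.82). MCL1 changed by −0.89 and BCL2L1, which encodes BCL-XL, by 0.69, while BID (0.33) and BOK (0.42) were not called; BCL2L1 lost its call without either control library or knockdown library 2. The remaining lists did not pass camera. NF-kB genes (2 rose and 2 fell of 10; library 2 above library 1 by 0.44 in the controls and 0.32 in the knockdown) had an adjusted p of 0.47, cholesterol (1 and 2 of 24) 0.26 (0.042 without knockdown library 2), fatty acids (1 and 2 of 25) 0.64, glutamine and serine (1 and 3 of 19) 0.88 and autophagy (2 and 2 of 25) 0.55. The ER unfolded protein response (0 and 1 of 18) had 0.64, complex I (2 and 1 of 37) 0.78, complexes III to V (1 and 0 of 35) 0.78, the mitochondrial ribosome (4 and 0 of 37) 0.14 (0.031 without control library 1), histones (0 and 0 of 10) 0.97 and epithelial markers (0 and 0 of 5) 0.66. For glutamine and serine genes the median was 0.07, the mean −0.03 and camera's direction down, and for histones −0.04, −0.08 and up.

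**Figure D2:**
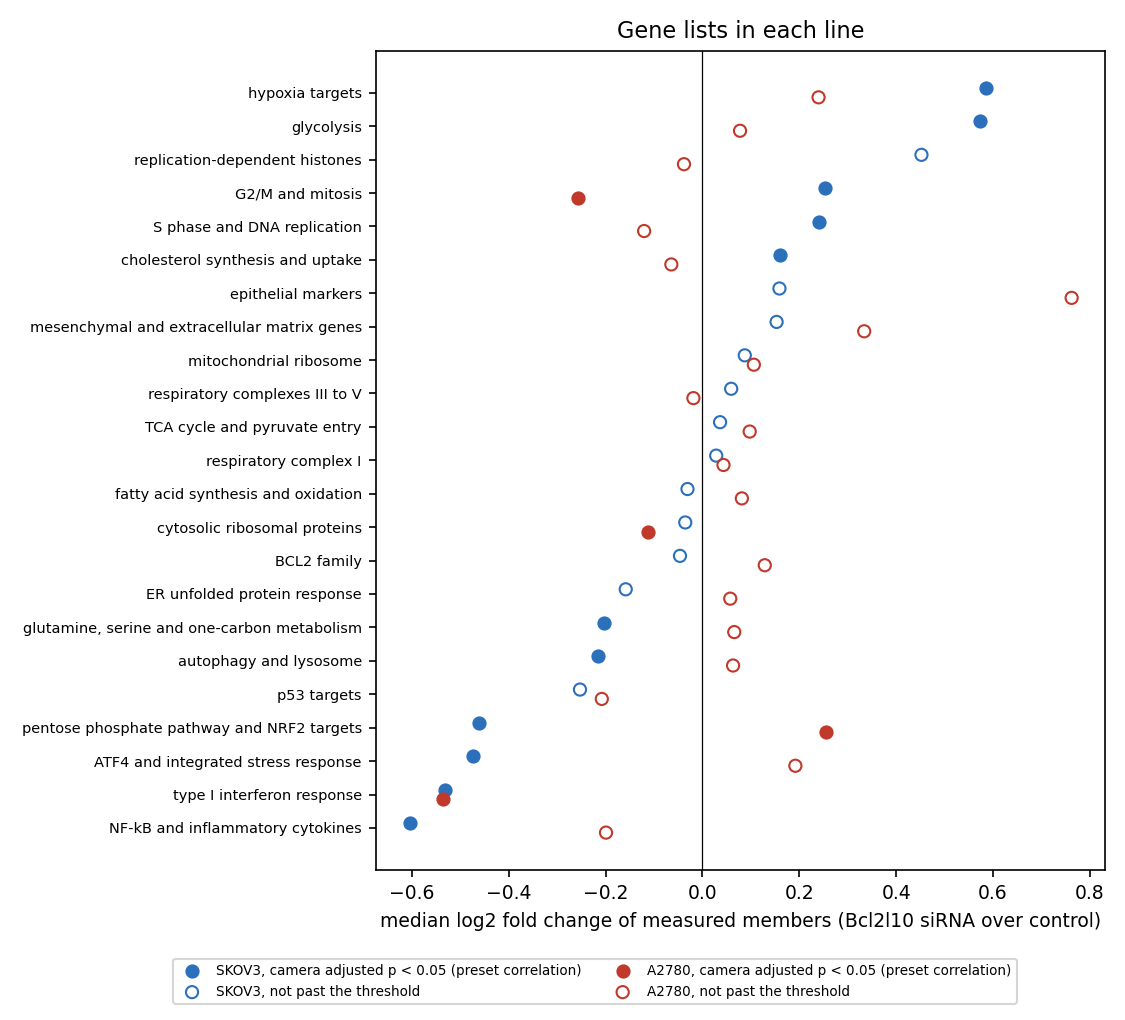
Median log2 fold change (Bcl2l10 siRNA over control) of the measured members of each gene list, in SKOV3 (blue) and A2780 (red). Filled points passed camera at the preset correlation (11 lists in SKOV3 and 4 in A2780). None of these calls held with an estimated correlation, a test with 2 residual degrees of freedom per line that few lists can pass. The estimate lay above the preset for every list called except NF-kB in SKOV3.

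The lines shared part of their response, more than expected for independent lists, though most SKOV3 calls were not called in A2780 as well. A missed threshold in A2780, where fewer genes were called, does not show that a gene did not change there. Among 10420 genes tested in both, 1178 were called higher in SKOV3 and 786 in A2780, and 1356 and 660 lower. Of these, 343 were higher in both lines (88.9 expected for independent lists) and 414 lower in both (85.9 expected), by Fisher's exact test with p = 9.4e-132 and 2.6e-217. Only 17 genes were higher in A2780 and lower in SKOV3, and 5 the reverse. Across 10369 genes without small RNAs, the fold changes of the lines correlated with a Pearson r of 0.53 and a Spearman rho of 0.46; genes are not independent replicates. Among genes lower in both, ELOVL4 (−2.18 in SKOV3), CLIC4 (−1.99), CD164 (−2.23), SDHD and LIN7C (−1.80) had the largest smaller fold. Among genes higher in both were TPM4, EMC6 (1.57 in A2780), the pseudogene ZNF702P (1.68 in SKOV3 and 1.55 in A2780), the opioid growth factor receptor gene OGFR (1.53 in each) and MED11 (1.73 and 1.33). The shared counts fell to 44 and 62 without A2780 control library 1, to 37 and 64 without A2780 control library 2, to 155 and 224 without A2780 knockdown library 2 and to 147 and 225 without SKOV3 control library 1. With a replicate block they were 661 and 730. Without SKOV3 control library 2, 197 genes were higher in both, and OGFR lost its A2780 call without either A2780 control library.

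**Figure D3:**
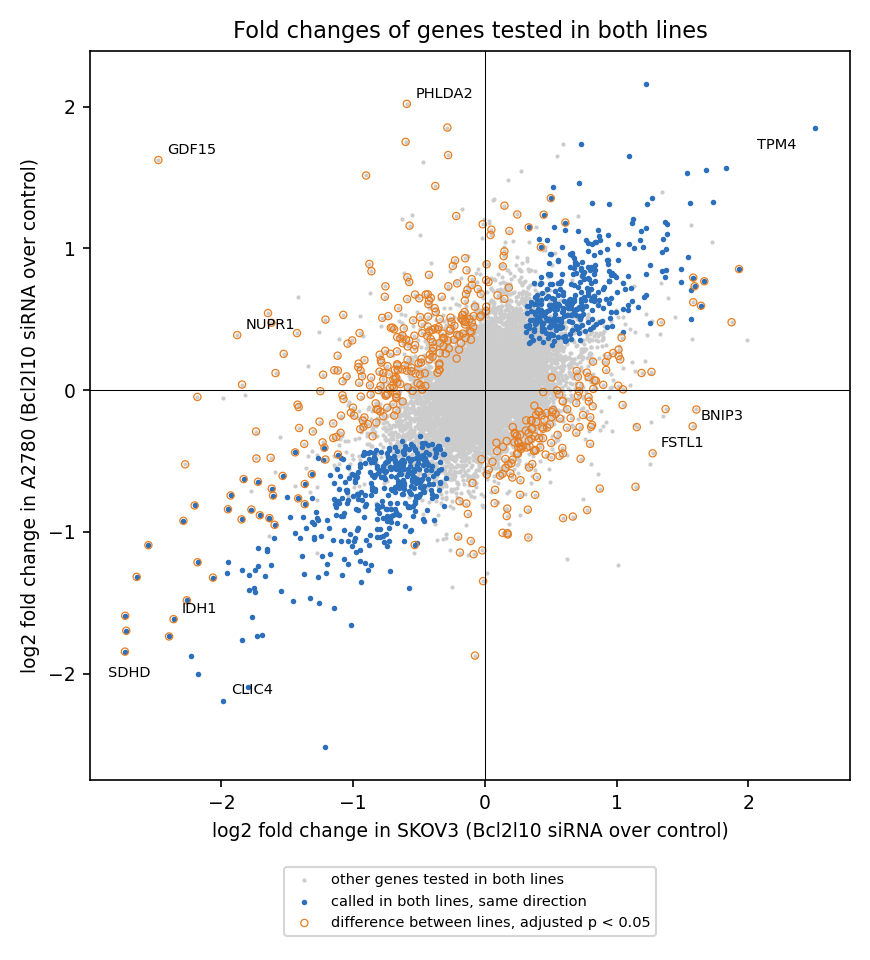
Log2 fold change after Bcl2l10 siRNA in SKOV3 (x axis) and A2780 (y axis), 1 point per gene tested in both lines, small RNAs left out. Blue points were called in the same direction in both lines, and orange circles mark genes whose effect differed between the lines; SDHD and IDH1 lie low in both, and GDF15 lies at −2.48 and 1.62.

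The size of the response differed between the lines for 459 of 10420 genes (limma, A2780 effect minus SKOV3 effect; 295 positive, 164 negative; 2537 at an unadjusted p under 0.05). GDF15 fell in SKOV3 and rose in A2780 (28.0 ± 11 to 86.8 ± 25.3 FPKM, log2 fold change 1.62), a difference of 4.10 (SE 0.45, adjusted p = 0.0082). PHLDA2 (−0.59 in SKOV3 and 2.02 in A2780), the uridine phosphorylase gene UPP1 (−0.90 and 1.51) and SPP1 (−0.60 and 1.75) also went opposite ways, with differences of 2.61, 2.42 and 2.35. NUPR1 differed by 2.27. In the other direction, BNIP3, a mitophagy receptor gene, rose in SKOV3 (1.58) with −0.25 in A2780, a difference of −1.83 (SE 0.33, adjusted p = 0.029, and 0.051 without a filter on low values). C1QL1 (−1.82), PRTG (−1.80), the sulfotransferase gene SULT1A1 (−1.74), which has close paralogs, and the follistatin-like gene FSTL1 (−1.72) followed. SDHD and IDH1 fell further in SKOV3, by differences of 0.89 (adjusted p = 0.035) and 0.75 (adjusted p = 0.048). The ATF4 list differed most among lists that were higher in A2780 (camera adjusted p = 2.2e-07, adjusted p = 0.075 with an estimated correlation). A fit without 1 library has fewer residual degrees of freedom and a group of 1 library, which by itself can lower the count. The GDF15 difference stayed between 3.70 and 4.50 in these fits. The count fell whichever library was left out. It was 30 without SKOV3 control library 1, 86 without SKOV3 control library 2, 142 and 72 without SKOV3 knockdown library 1 and 2, 81 and 113 without A2780 control library 1 and 2, and 253 and 93 without A2780 knockdown library 1 and 2. With a replicate block it was 742. Without SKOV3 control library 1, the calls of GDF15 (adjusted p = 0.051), UPP1 (0.059), BNIP3, C1QL1, PRTG and FSTL1 were lost; BNIP3, C1QL1 or PRTG lost theirs without every other library but A2780 knockdown library 1. Within the lines, the A2780 rises of GDF15 and UPP1 were not called without A2780 control library 1, nor the SKOV3 falls of PHLDA2 without SKOV3 control library 1 and of SPP1 without either SKOV3 control library or knockdown library 2.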

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

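Each difference below was tested in the fit planned for the contrast between the lines, and the scaling and depth tests of the ATF4 list were written before their results were seen. Which list to weigh was chosen after the differences were seen.

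The siRNA effect differed between A2780 and SKOV3 (A2780 minus SKOV3, log2) for 459 of 10420 genes by limma, and the named genes among them follow. Stress and amino acid genes had the higher effect in A2780: GDF15 differed by 4.10, NUPR1 by 2.27, PHGDH by 2.13, ATF3 by 1.78, WARS by 1.75, TRIB3 by 1.73 and DDIT3 by 1.28. So did NRF2 targets, with TXNRD1 at 1.01, SRXN1 at 1.00, NQO1 at 0.84 and SLC7A11 at 0.69. Among autophagy and lysosome genes, SQSTM1 differed by 1.15, LAMP2 by 0.84 and BECN1 by 0.57. PHLDA2 differed by 2.61, UPP1 by 2.42, SPP1 by 2.35, IER3 by 2.14, TNFAIP3 by 2.10, SMOX by 1.94 and BHLHE40 by 1.15. Genes that fell in both lines, but further in SKOV3, were ATP6V1D (1.46), C14orf142 (1.37), SWAP70 (1.33), FERMT2 (1.14), CCNG1 (1.11), EIF4G2 (1.02), MXI1 (0.97), SDHD (0.89), IDH1 (0.75) and ENOPH1 (0.66).

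Cell cycle genes had the lower effect in A2780, with NUSAP1 at −1.37, RRM2 at −0.84, KIF2C at −0.70, TYMS at −0.66 and TPX2 at −0.57. So did BNIP3 (−1.83), P4HA1 (−1.41), BNIP3L (−1.14), GPI (−0.69) and FDPS (−0.62). C1QL1 differed by −1.82, PRTG by −1.80, SULT1A1 by −1.74, FSTL1 by −1.72, TNNT2 by −1.39 and GANAB by −1.07.

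Camera at the preset correlation gave a difference between the lines for 10 lists. The effect was higher in A2780 for ATF4 genes (adjusted p = 2.2e-07), pentose phosphate and NRF2 genes (5.6e-06), autophagy (0.00056), glutamine and serine (0.0041), the ER unfolded protein response (0.0055) and NF-kB (0.016). It was lower for G2/M (1.8e-07), S phase (8.2e-06), cholesterol (0.00032) and glycolysis (0.0026). None of the 10 differences passed with an estimated correlation, the lowest adjusted p being 0.075 for ATF4 genes and 0.0827 for pentose phosphate and NRF2 genes.

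The members of the ATF4 list differed between the lines by a median of 0.54. Scaling between libraries is argued against, since under median-of-ratios and quantile scaling the median stayed at 0.54 and 0.53. The knockdown libraries were shallower in SKOV3 and deeper in A2780. The list's median lay at percentile 100 of 10000 lists matched on mean expression, whose highest was 0.32. The list was picked for its difference, so that percentile was nearly fixed beforehand and does not test depth. A depth effect set by mean expression alone would have moved the matched lists as well, and none reached 0.54. That argues only against such an effect as the whole cause. Depth acting in another way was not tested and stays open. A different stress response of the lines to the same siRNA may underlie the difference and was not tested. Culture conditions and a different strength of off-target repression in each line stay open too.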

How the results depend on the processing

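All alternatives were planned before the data were examined except leaving out small RNAs, the crossed pairing in SKOV3, the fold threshold and the TCA cycle list without SDHD and IDH1, which were chosen after seeing the data. Count tools were not run, since the tables hold no counts.

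SDHD and IDH1 kept their direction under all alternatives run. Leaving out 1 library gave −2.85 to −2.61 for SDHD and −2.44 to −2.29 for IDH1 in SKOV3, and −1.98 to −1.71 and −1.77 to −1.46 in A2780, all past the threshold. Without a filter on low values their A2780 values of −1.84 (SDHD) and −1.61 (IDH1) missed it (adjusted p = 0.0553); more genes were then tested, and the cause was not tested further. That setting gave 1356 genes in SKOV3 and 4 in A2780. One fit over all 8 libraries gave 2485 in A2780. A log2 fold change of at least 1 left 449 genes in SKOV3 and 209 in A2780. The other scalings, pseudocounts, filter and variance models left every count of genes within 1.5 times. Pseudocounts changed no call of a named gene, and no named gene changed direction under any alternative. In A2780, 10 of 67 named genes lost no call under any alternative run, and in SKOV3 64 of 79; genes with no call to lose are among them.

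The replicate block gave 4667 genes in A2780, 742 for the difference, and 661 higher and 730 lower in both lines. The labels do not say that equal numbers pair libraries. The authors' columns do give log2 fold changes between libraries of equal number, without stating what such libraries shared. On simulated data without a batch, this fit recovered 0% of planted changes in each line. That simulation held no deviation shared by the genes of a library, so its 0% does not carry over to these libraries. In SKOV3 the block gave 3107 genes and the crossed pairing 3581. Histones in A2780 turned direction with the block (adjusted p = 0.995).

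Leaving out 1 library gave 906 to 2545 genes in SKOV3, 161 to 1136 in A2780, 30 to 253 for the difference, 37 to 324 higher in both lines and 62 to 366 lower in both. A group left with 1 library was assumed to vary like the other. These fits also have fewer residual degrees of freedom, which by itself can lower the counts. In SKOV3, 11 lists were called, against 0 with an estimated correlation and 4 with fry, of which 3 were among the 11 and the other was the ER unfolded protein response (0.041). In A2780, 4 were called, against 0 and 0. Without SDHD and IDH1, the TCA cycle list turned direction in SKOV3 (0.635), since both genes fell. Fry turned the direction of mesenchymal genes in SKOV3 (0.548) and the BCL2 family in A2780 (0.959).

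Some lists that were not past the threshold turned direction when a library was left out. Their adjusted p over the left-out libraries in SKOV3 ran from 0.591 to 0.98 for the TCA cycle, 0.757 to 0.98 for the BCL2 family, 0.399 to 0.890 for fatty acids, 0.234 to 0.818 for cytosolic ribosomal proteins and 0.198 to 0.935 for mesenchymal genes. In A2780 they ran from 0.727 to 0.957 for complex I, 0.830 to 0.931 for complexes III to V, 0.737 to 0.957 for glutamine and serine, 0.727 to 0.980 for the BCL2 family, 0.823 to 0.957 for histones and 0.132 to 0.931 for autophagy. The cause was not tested. Depth limits low genes, since a value near an FPKM of 0.0456 can rest on few fragments.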

Other observations

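Tests of the siRNA's other strand, of UTR length and GC content, of depth in genes lower in both lines, of loss of the transcript and of the A2780 batch were chosen after the results were seen. The guide strand test was written before.

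Genes with certain words of 7 bases in the 3' UTR were lower in both lines. Of all words of this length, GGCTGTT ranked 1st for lower fold changes in SKOV3 (effect −0.18, SE 0.012, t = −15.1, 1618 genes) and in A2780 (−0.14, SE 0.011, t = −12.9, 1528 genes). ATTTATC ranked 3rd and 2nd, and TTTATCA 2nd and 3rd. The highest absolute t over 20 shuffles of the fold changes was 4.8 in SKOV3 and 4.5 in A2780. Genes with ATTTATC or TTTATCA alone, with GGCTGTT or GCTGTTA alone, and with both kinds had mean log2 fold changes of −0.13, −0.11 and −0.25 in SKOV3, against 0.07 with neither. In A2780 these were −0.08, −0.04 and −0.17, against 0.07. Of the 414 genes lower in both lines, 393 had a 3' UTR sequence and 84.7% of those held at least 1 of the 4 words (51.9% expected at like UTR length, highest of 10000 draws 61.1%). Of the genes higher in both, 24.8% did (37.8% expected). The 4 words were picked from the same fold changes, so these shares are not independent evidence.

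SDHD, ATP6V1D and ENOPH1 hold ATTTATC or TTTATCA in the 3' UTR, and CLIC4, ELOVL4, EIF4G2, FERMT2 and SWAP70 hold words of both kinds. Some named genes that rose in SKOV3 hold words too. CCDC80, BNIP3 and FSTL1 hold both kinds, and COL8A1 holds ATTTATC or TTTATCA. IDH1, CXCL8, GDF15 and WARS hold none of the 4. Among the 10 largest falls, 6 of 9 with a 3' UTR held a word in SKOV3 and 7 of 10 in A2780. Among the 10 largest rises, 2 of 10 and 0 of 10 did. These shares were not matched on UTR length. On the higher side, TCGGAGA (t = 8.74 in SKOV3, 7.60 in A2780) and GGAGAAA (7.05 and 9.02) took the first places.

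The siRNA sequence is not given in the labels, and a candidate explanation of the genes lower in both lines is repression through seed matches of the siRNA itself. The guide strand alone is argued against, by the bound written beforehand, since the word ranked 1st lies in 0 of 2 BCL2L10 transcripts. Both strands of one 19-base duplex would put the reverse complement of the other strand's word 10 bases before the guide word, and in BCL2L10 that of GGCTGTT starts 10 bases before ATTTATC. GGCTGTT was picked in the model with UTR length and GC terms, so its rank there could not test them. Its weaker t with those terms, −12.9 in A2780, lay past the highest absolute t of 4.5 over the shuffles. That argues against UTR length and GC content, as modelled, as the whole cause. The shuffles break any tie of fold change to UTR composition, so composition beyond these terms stays open. In A2780 the higher-side words GGAGAAA (t = 9.02) and TCGGAGA (7.60) passed the shuffles too. Without the terms the word's rank was 3 in SKOV3 and 43 in A2780. Depth differed in opposite directions in the lines, which argues against it as the whole cause (the correlation of 0.53 across genes restates the pattern). Loss of the BCL2L10 transcript was predicted to show as an FPKM above 0 in the controls of both lines. That was not seen, since both A2780 control libraries were at 0. With a highest FPKM of 0.0456, values this near the floor do not decide, and by them loss of the transcript cannot be told apart from the other explanations. Loss alone does not predict the words or their 10-base spacing in BCL2L10, but it does not forbid them either. It therefore stays open as a part of the cause.

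The site that fits is CAACAGCCTTCATTTATCT, at bases 627 to 645 of a BCL2L10 transcript of 1249 bases. It lies in exon 2 of 2, in coding sequence, on the minus strand of chromosome 15 (GRCh38, 52109867 to 52109885). A single word's presence in the transcript is weak evidence, since the higher-side word GGAGAAA lies there too, and so does the reverse complement of TCGGAGA. For SDHD, a direct effect of the siRNA on its transcript may therefore be weighed against regulation by BCL2L10, and the 10-base spacing does not decide between these for a single gene. An siRNA of another sequence or a rescue would.

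In A2780, libraries of the same number deviated alike from their group means across tested genes other than small RNAs. Across tested genes without small RNAs the deviations correlated at 0.61, against −0.18 in SKOV3. With the small RNAs, 99 of 11569 tested genes and of unreliable FPKM, the correlation was 0.03, against 0.16 across all tested genes in SKOV3. Type I interferon genes were higher in library 2 of both groups (0.52 and 0.56) and G2/M genes lower (−0.25 and −0.26). The main A2780 test did not model such a shared deviation, which bears on its 1581 calls. With a replicate block, which models it, all 1581 were called in the same direction, among 4667 calls. Whether a batch shared by libraries of the same number is the source of the shared deviation stays open, since the labels name none. No biological explanation was tested.

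In the authors' deposited tables, 3723 genes had a p under 0.05 in SKOV3 and 2609 in A2780. Of the limma calls, 2721 of 3016 and 1452 of 1581 were among them.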
